A study of Mus musculus with 4 samples.

How the data were processed

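The data are mRNA sequencing of CD45-depleted lung tumour cells from KP mice (activated Kras and deleted Trp53, 2 libraries) and KP25 mice (the same with Usp25 deleted, 2 libraries), collected 10 weeks after Ad-Cre. The sample labels and the series design give these genotypes, but the growth protocol names KP and KP25 mice for the Ad-Cre dose and then KL and KL25 mice for the tumour collection. Whether that is a slip of wording was not settled, and the genotype labels were used as given. The series design gives 2 mice per genotype, so the spread between libraries is read as spread between mice. Per the labels' protocols, suspensions made with a tissue dissociator were incubated with CD45 magnetic beads, RNA was taken up in TRIzol, libraries were made with a stranded mRNA kit and sequenced on a NovaSeq instrument. Per the labels' protocols, reads were trimmed with cutadapt and aligned to GRCm38, and reads per gene were counted with HTSeq; the submitters' processing notes name both GRCm38 and GRCm39. The aligner, the annotation release and the strand setting of the counting are not given in the sources used here, so values of overlapping genes, antisense genes and near-identical copies such as Hbb-bs and Hbb-bt are uncertain.

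One table of 21931 rows was used, with gene symbols as the only identifiers. It holds a deposited value for each of the 4 libraries and, per the file headers, a baseMean and the authors' own comparison as a log2 fold change, a p-value and an adjusted p. No header or label names the unit of the per-library columns. That the authors made them as FPKM was worked out from the values: their columns sum to unequal totals, and together with the baseMean they resolve into whole reads. The test behind the authors' log2 fold changes is not named in the sources used here, and values printed from it are credited to the authors' deposited table. Of the rows, 4201 are at 0 in all libraries, and 20 names occur on more than 1 row, where the row with the highest mean FPKM kept the name. Of 21909 distinct names, 21257 are in GENCODE vM21, from which the coordinates of Usp25 (GRCm38, 1-based) were taken. The number of reads behind each FPKM value was recovered by combining the FPKM steps with the authors' baseMean and fold changes. All of the 65974 values above 0 came out whole within 0.01 reads, the largest distance being 0.00115. Recovered totals were 13477207 reads for KP replicate 1, 14862698 for KP replicate 2, 14528923 for KP25 replicate 1 and 14084108 for KP25 replicate 2. At this depth 3 reads on a transcript of 1 kilobase correspond to between 0.202 and 0.223 FPKM, the limit a value of 0 allows, which covers counting error only. The 10 most abundant genes took between 6.52% and 10.5% of reads.

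The design set before the data were examined had assumed a table of counts. As the table holds FPKM, the test named there for normalised values was used: limma 3.58.1 in R 4.3.3, with the intensity trend and robust estimation, on log2(FPKM + 1) of genes with at least 1 FPKM in at least 2 libraries, with genotype as the only term. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and also with an absolute log2 fold change of at least 1. Gene lists were tested with limma's camera with a preset inter-gene correlation of 0.01, for lists with at least 5 tested members and adjusted over the 42 lists tested. The 44 lists, written from general knowledge before the data were examined, hold markers of cell types that a lung tumour suspension can contain, tumour states, pathways and signs of handling. Of these, the basal and neuroendocrine markers and the sex-linked transcripts had too few tested members. Camera with an estimated correlation and fry, which asks of each list by itself whether its genes move one way on balance, were run beside it. Some genes sit in more than one list.

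The genes named were fixed by rule before the data were examined: Usp25, Usp28, Kras, Trp53 and Ptprc, then genes past the threshold (there were none), then up to 4 members of each list with the smallest p, and the first gene of each list. Apob, P2rx2, Cfi and Onecut2 are named because the authors' deposited table calls them, and genes named only in the closing section were chosen after their values were seen.

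The procedure was tested on simulated data for KP25 against KP, with 200 genes changed by known folds. The changed genes were drawn from those with an expected mean of at least 100 reads, and all genes of a group were given the same spread. The rates below therefore do not cover genes with fewer reads, or spreads that differ between genes. With the spread of the KP25 pair in both groups, 98% of the genes changed 2-fold and 100% of those changed 4-fold or more were recovered among 12707 genes tested, with 15 false calls. With each pair's own spread, 2.04% of the 4-fold, 30.6% of the 8-fold and 52.1% of the 16-fold changes were recovered among 12725 genes tested, none of the 2-fold changes, and there were 0 false calls. None of 20 unchanged lists was called. Genes were simulated independently of each other, so this does not show how often lists whose members move together are called by mistake.

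Alternatives set before the data were examined were the authors' size factors in place of library totals, a pseudocount of 0.1, no filter, a filter of 1 FPKM in all 4 libraries, no robust estimation, the replicate number as a block, leaving out each library in turn, and for the lists an estimated correlation, fry and ranks. Those written for counts were carried over to FPKM where they had a counterpart. Added after seeing the data were limma-voom on the recovered reads (genes with at least 10 reads in at least 2 libraries), a fit without the trend, and the other splits of the 4 libraries. Tests of explanations and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.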

Results

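Messenger RNA was sequenced from lung tumour cell suspensions of 2 kinds of mice, 10 weeks after Ad-Cre, an adenovirus that carries the Cre recombinase, had been given through the nose. In KP mice, Cre switches on an activated Kras allele and removes floxed Trp53, which gives lung adenocarcinoma. KP25 mice carry the same alleles and in addition lack Usp25, a deubiquitinase, which removes ubiquitin from proteins. Tumours were dissociated and treated with CD45 magnetic beads to deplete leukocytes, and the remaining cells were profiled, with 2 libraries per genotype. The comparison of KP25 with KP asks how loss of Usp25 alters the transcriptome of these cells. The deposited values were FPKM (fragments per kilobase of transcript, scaled to library depth). The reads recovered from them came to 13477207 for KP replicate 1, 14862698 for KP replicate 2, 14528923 for KP25 replicate 1 and 14084108 for KP25 replicate 2. Genes above 0 numbered 16583, 16540, 16454 and 16397 in the same order.

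Usp25 itself separated the genotypes as the labels state. Its level was 13.9 and 13.6 FPKM in the KP libraries and 2.72 and 2.90 FPKM in the KP25 libraries, or 13.8 ± 0.213 against 2.81 ± 0.126 (SD, n = 2 each), a log2 fold change of -1.95 (SE 0.159) on the log2(FPKM + 1) scale. The fold of the means was 4.89, and 214 and 221 reads remained in the KP25 libraries against 1014 and 1094 in the KP libraries. The gene lies on chromosome 16 from 77013706 to 77116780 on the plus strand (GRCm38). Gene-level values do not show which exons the remaining reads came from. In the test over all genes Usp25 did not pass, with an adjusted p of 0.776 (limma). With either KP library left out, the spread comes from the KP25 pair alone and the single KP library is assumed to vary like it. Fitted so, the adjusted p was 0.00518 without KP replicate 2 and 3.55e-05 without KP replicate 1, and with a KP25 library left out it was 1.00 (limma). Usp28, the closest relative of Usp25, was 3.98 and 2.20 FPKM in KP and 3.58 and 3.85 FPKM in KP25.

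Kras transcript was 27.1 and 46.6 FPKM in KP against 23.6 and 26.5 FPKM in KP25, and Trp53 was 14.0 and 5.42 FPKM against 12.7 and 11.3 FPKM. Ptprc, which encodes CD45, was still detected after the depletion: 13.3 FPKM in KP replicate 1, 2.51 FPKM in KP replicate 2 and 12.9 and 12.7 FPKM in KP25. For these 3 genes the KP25 pair and KP replicate 1 lay close together and KP replicate 2 lay apart, a layout that recurred over the transcriptome. The correlation of log2(FPKM + 1) across genes, which are not independent replicates, was 0.990 between the KP25 libraries, 0.984 and 0.987 between KP replicate 1 and each of them, and 0.870 between the KP libraries. The KP libraries differed by at least 2-fold in 2338 genes and the KP25 libraries in 43 genes.

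**Figure D1:**
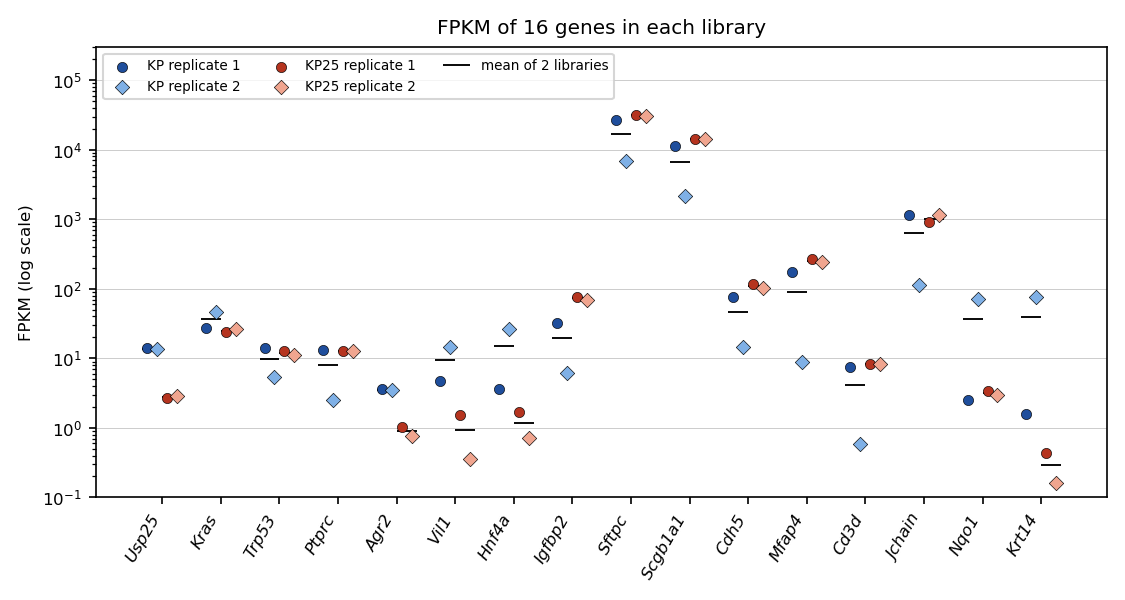
FPKM on a log axis (vertical) of 16 genes in each of the 4 libraries, with circles for replicate 1, diamonds for replicate 2, blue for KP, red for KP25 and a black line at each group's mean of 2 libraries. Usp25 separates the genotypes at 13.9 and 13.6 FPKM against 2.72 and 2.90 FPKM, while for Sftpc, Mfap4, Cd3d, Jchain and Nqo1 it is KP replicate 2 that lies away from the other 3 libraries.

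No gene passed an adjusted p of 0.05 among 12691 tested (limma, smallest adjusted p 0.776), and none passed at a fold of 2. At an unadjusted p under 0.05 there were 218 genes, where chance alone gives 635, and 178 with limma-voom on the recovered reads, which also called 0. Of the 218, 40 were higher and 178 lower in KP25, whereas the authors' deposited table has the opposite balance, with 177 genes marked up and 47 marked down at an unadjusted p under 0.05 and a fold of at least 2. With 1 KP library set against the KP25 pair, and the spread taken from that pair alone, 15 genes passed for KP replicate 1 (2 higher and 13 lower in KP25) and 6740 for KP replicate 2, so these counts compare single libraries and not genotypes. With 2 libraries per group an exact two-sided permutation test cannot go below p = 0.333, so single genes are given below as values. The authors' deposited table lists 6 genes with an adjusted p under 0.05. Of these, 5 were lower in KP25 by the log2 fold change of that table: Onecut2 at -4.42, Apob at -4.33, P2rx2 at -3.75, Cfi at -2.36 and Usp25 at -2.23. Igfbp2, which encodes an insulin-like growth factor binding protein, was higher at 1.98. Apart from Usp25 and Igfbp2 these genes were chosen after their values were seen. In the FPKM columns Apob, the structural protein of liver and gut lipoproteins, stood at 10.7 and 5.78 FPKM in KP and 0.662 and 0.117 FPKM in KP25. Cfi, complement factor I, stood at 23.5 and 17.9 FPKM against 6.26 and 1.47 FPKM. P2rx2 was 5.48 and 9.20 FPKM against 0.722 and 0.331 FPKM, and Onecut2, at 0.498 and 0.560 FPKM against 0.0170 and 0.0306 FPKM, lay under the level needed for testing here. Igfbp2 was 32.7 and 6.19 FPKM in KP and 75.8 and 69.3 FPKM in KP25.

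Groups of genes were then compared through lists of cell type markers, tumour states and pathways. Of 42 lists with enough tested members, 25 passed the list test, 18 higher and 7 lower in KP25 (limma camera, preset correlation). With an estimated correlation 0 of the 42 passed, the smallest adjusted p being 0.670, and within-list correlations reached 0.988. Correlation alone does not account for this loss. The alveolar type 1 list, estimated at -0.03 and so below the preset, went from an unadjusted p of 0.000301 to 0.0610 (camera). A list that failed this setting is therefore not shown to be unchanged. The 0.670 given below is a value that many lists share after adjustment, and it does not rank them. Without KP replicate 2, which again leaves only the KP25 pair to give the spread, 10 lists passed, and 8 of them were among the 25 and had the same direction. Those 8 are markers of endothelium, gastric and gut-like tumour cells, erythroid cells, alveolar type 1 cells, alveolar type 2 cells and macrophages, the mitochondrially encoded genes and the immediate early genes. In no list did a member pass over all genes, and only Agr2 passed when adjusted over the list alone. That adjustment does not allow for the search through 42 lists, so a single such gene can arise by chance.

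The gastric and gut-like tumour markers, genes of digestive epithelium that lung adenocarcinoma cells can take up, were lower in KP25 in 11 of 12 tested members, with a median log2 fold change of -1.33. Agr2, a chaperone of mucin-secreting cells, was 3.53 ± 0.0506 FPKM in KP and 0.891 ± 0.172 FPKM in KP25 (SD, n = 2 each), a log2 fold change of -1.26 (SE 0.206). Its adjusted p was 0.776 over all genes and 0.0409 adjusted over the list alone (limma). These values rest on few reads, 62 and 67 in KP and 19 and 14 in KP25. Vil1, the microvillus protein villin, was 4.79 and 14.3 FPKM in KP and 1.51 and 0.360 FPKM in KP25. Foxa3 was 1.60 and 3.93 FPKM against 0.507 and 0.383 FPKM, and Gpa33, a surface antigen of gut epithelium, was 4.57 and 43.97 FPKM against 0.879 and 0.699 FPKM. Hnf4a, a master regulator of gut and liver epithelium, was 3.61 and 26.8 FPKM against 1.67 and 0.721 FPKM. In 8 of the 12 members both KP libraries lay above both KP25 libraries, a layout that chance gives for 16.7% of genes and that 25.9% of all tested genes had, and in 9 KP replicate 2 was the highest of all. Only 12 of the 20 members of the list met the filter. Foxa3 and Gpa33, under 1 FPKM in both KP25 libraries, met it only through the KP libraries and had to show this layout. The fit without KP replicate 2 kept the same genes. The list passed at an adjusted p of 2.06e-05 (camera), against 0.670 with an estimated correlation, and passed without KP replicate 2 at 1.06e-06, with a smaller median of -0.72.

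Alveolar lineage markers were higher in KP25. Of the 19 alveolar type 2 markers, genes of the surfactant-producing cell from which these tumours mostly arise, 15 had a positive log2 fold change, with a median of 0.60. Sftpc, surfactant protein C, was 27054.5 FPKM in KP replicate 1, 6858 FPKM in KP replicate 2 and 31477 and 30720 FPKM in KP25. Lyz1 was 85.9 and 44.2 FPKM in KP against 106 and 115 FPKM in KP25, and Chia1 was 123 and 5.13 FPKM against 257 and 212 FPKM. Nkx2-1, the lineage factor of lung epithelium, had the opposite sign, at 189 and 220 FPKM in KP and 130 and 143 FPKM in KP25. Of 15 alveolar type 1 markers 12 were positive, with a median of 0.25. They include Igfbp2, Pdpn at 40.1 and 22.8 FPKM in KP against 51.7 and 51.1 FPKM in KP25, and Clic5 at 42.9 and 24.9 FPKM against 56.9 and 52.3 FPKM, whereas Ager was 494 and 794 FPKM against 699 and 625 FPKM. The type 2 list passed at an adjusted p of 0.000402 and the type 1 list at 0.000844 (camera), both against 0.670 with an estimated correlation, and at 0.00157 and 1.47e-07 without KP replicate 2, where the medians were 0.13 for type 2 and 0.33 for type 1.

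The advanced tumour state markers, which mark less differentiated tumour cells, were lower in KP25 in 14 of 17 members, at a median of -0.80. Clu was 575 and 1285 FPKM in KP against 412 and 369 FPKM in KP25, Hmga1 was 27.8 and 120 FPKM against 22.1 and 19.6 FPKM, and the claudin Cldn4 was 15.2 and 152 FPKM against 10.8 and 12.6 FPKM. Epithelial adhesion genes were lower in 17 of 19 members, at a median of -0.35. Epcam was 78.5 and 223 FPKM in KP against 79.0 and 78.6 FPKM in KP25, and Elf3 was 18.2 and 25.8 FPKM against 13.5 and 14.5 FPKM. The epithelial to mesenchymal transition genes were higher in 13 of 16 members, at a median of 0.51, with Vim at 179 and 50.9 FPKM against 200 and 200 FPKM. Fibroblast and matrix markers, none of them in that list, had a larger median of 1.11 in the same direction, so the values do not show which cells the transition genes came from. Adjusted p values were 0.0368, 0.0106 and 0.000644 in this order (camera), each against 0.670 with an estimated correlation. None of the 3 passed without KP replicate 2, where the medians were -0.03, 0.04 and 0.10 in the same order. The test direction of the first 2 turned, although the median of the advanced state list stayed just negative. The advanced state list also missed the threshold when at least 1 FPKM was required in all 4 libraries (0.0619). Of the basal and neuroendocrine markers only 2 reached the level needed for testing, too few for a list test: the basal keratin Krt14 was 1.56 and 76.3 FPKM in KP and 0.431 and 0.162 FPKM in KP25, and Calca was 1.15 and 0.440 FPKM against 0.490 and 1.90 FPKM.

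Markers of other cells in the tumour were higher in KP25, with large gaps inside the KP pair. All 19 endothelial markers were positive, at a median log2 fold change of 1.07, and in 15 both KP25 libraries lay above both KP libraries, against 16.7% of genes by chance and 14.3% of all tested genes. Kdr, the main receptor for vascular endothelial growth factor, was 16.4 and 4.59 FPKM in KP against 27.8 and 22.9 FPKM in KP25, Cdh5 was 77.4 and 14.5 FPKM against 115 and 104 FPKM, and Gpihbp1, a protein of capillary endothelium, was 21.3 and 20.7 FPKM against 33.9 and 32.9 FPKM. All 19 fibroblast and matrix markers were also positive, at a median of 1.11, with Postn at 27.9 and 10.6 FPKM against 39.6 and 37.6 FPKM and Mfap4 at 172 and 8.82 FPKM against 268 and 241 FPKM. The list of smooth muscle and pericyte markers was positive in 12 of 13 members and the ciliated cell list in all 17, the latter with Foxj1 at 25.3 and 4.59 FPKM against 22.5 and 24.98 FPKM. Rgs5, a pericyte gene, had the other sign at 6.14 and 24.1 FPKM in KP against 4.03 and 3.84 FPKM in KP25. The adjusted p was 4.80e-09 for endothelium, 1.18e-05 each for fibroblasts and ciliated cells and 0.00282 for smooth muscle (camera), all against 0.670 with an estimated correlation. KP replicate 2 was the lowest library for all endothelial and fibroblast members. Without it the endothelial median was only 0.27 and the ciliated median 0.08. The fibroblast and smooth muscle medians turned negative, at -0.11 and -0.21. The test direction turned to lower for smooth muscle and stayed higher for fibroblasts.

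Leukocyte markers remained after CD45 depletion, and the lymphocyte lists shared with the endothelial and fibroblast lists that KP replicate 2 lay lowest. In the rest of the layout they differed from the endothelial list more than from the fibroblast list. Both KP25 libraries lay above both KP libraries in 4 of 16 T and NK markers and 0 of 12 B and plasma cell markers. The counts were 15 of 19 endothelial and 6 of 19 fibroblast markers, against 14.3% of all tested genes. Without KP replicate 2 the median was -0.11 for fibroblast markers, -0.16 for T and NK markers and 0.27 for endothelial markers. All 16 T and NK cell markers and all 12 B and plasma cell markers were positive, at medians of 1.00 and 0.96, and KP replicate 2 was lowest for each of them. Cd3d of the T cell receptor complex was 7.56 and 0.593 FPKM in KP against 8.15 and 8.37 FPKM in KP25. Gzma, a granzyme of cytotoxic lymphocytes, was 4.57 and 0.936 FPKM against 16.2 and 8.05 FPKM, and Jchain of antibody-secreting cells was 1136 and 115 FPKM against 905 and 1138 FPKM. Macrophage and monocyte markers were positive in 14 of 20 members, at a median of 0.17, with Csf1r at 19.9 and 11.96 FPKM in KP against 23.2 and 25.3 FPKM in KP25, and Cd68 at 57.3 and 62.9 FPKM against 66.5 and 62.5 FPKM. Erythroid markers were positive in all 7 members, at a median of 0.92, with Hbb-bs at 536 and 277 FPKM against 1203 and 562 FPKM. KP25 replicate 1 lay highest for this list, at a median of 0.90 log2 units from the mean of the 4 libraries. KP25 replicate 2 was at 0.06 and KP replicate 1 at 0.01, so without KP replicate 2 the difference comes mainly from KP25 replicate 1. The adjusted p was 6.03e-05 for T and NK cells, 0.00111 for B and plasma cells, 0.00903 for macrophages and 0.000113 for erythroid cells (camera), all against 0.670 with an estimated correlation. Without KP replicate 2 the lymphocyte lists turned in sign and did not pass (0.692 and 0.0620), while the macrophage list passed at 0.0290 with a median of 0.09 and the erythroid list at 0.00167 with a median of 0.40. Neutrophil markers, positive in 9 of 12, did not pass (0.118), and there KP25 replicate 1 lay apart while KP replicate 2 was lowest in only 5 members.

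**Figure D2:**
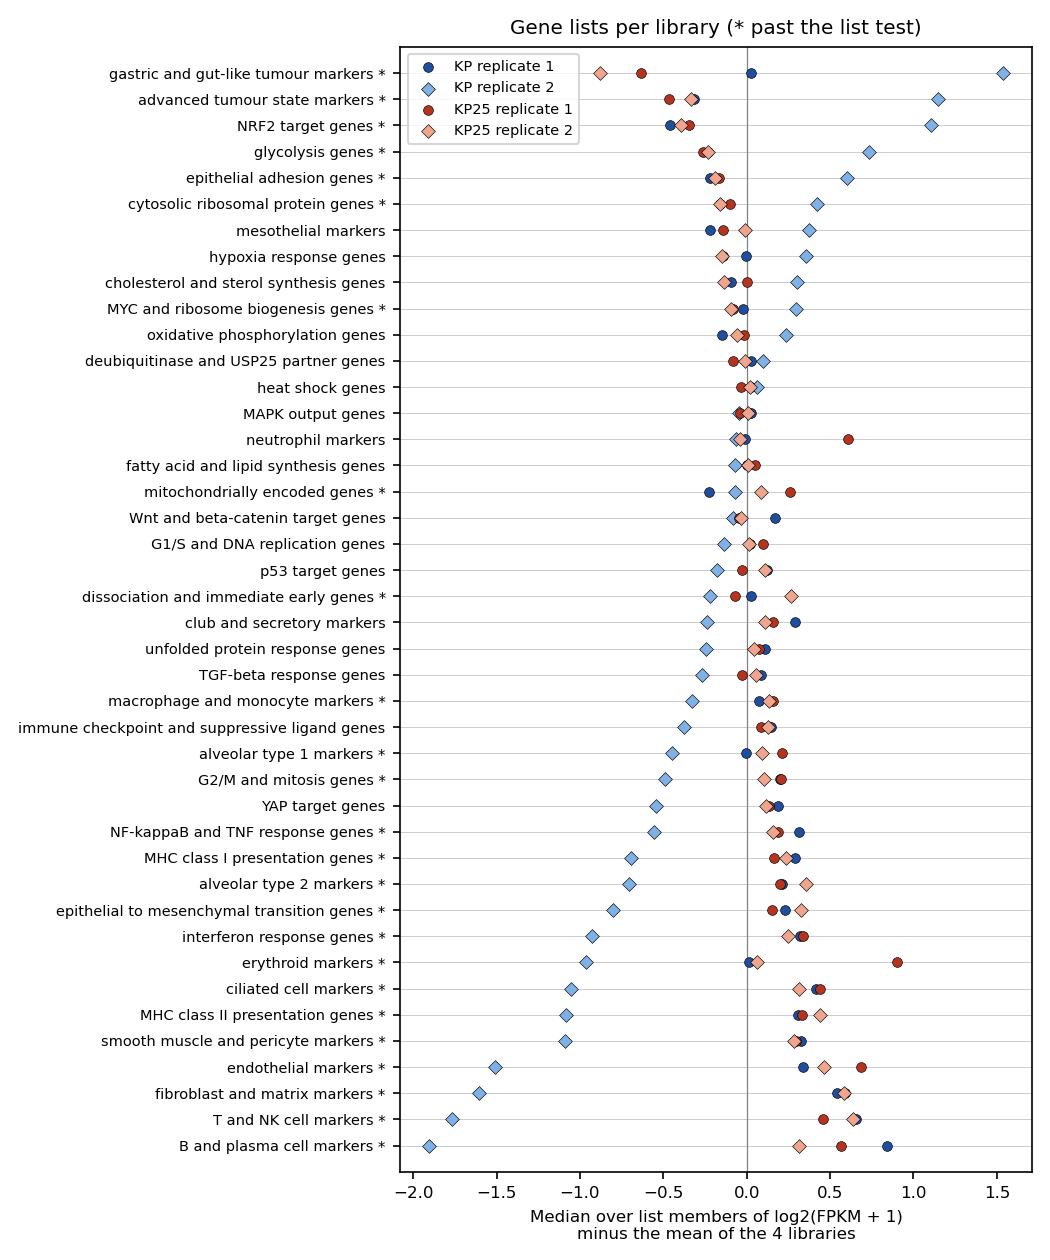
For each of 42 gene lists (vertical), the median over its members of log2(FPKM + 1) minus the mean of the 4 libraries (horizontal), one point per library, with an asterisk on the 25 lists that passed the list test with the preset correlation. In most lists KP replicate 2 (light blue diamonds) lies apart and the other 3 libraries lie together, while in the gastric and gut-like list KP replicate 1 also lies above both KP25 libraries.

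Antigen presentation and inflammatory genes were higher in KP25 as lists. The MHC class II genes were positive in all 15 members, at a median of 0.78, with H2-Ab1 at 473 and 154 FPKM in KP against 489 and 541 FPKM in KP25. Markers of B, T and NK cells were also lowest in KP replicate 2, with larger medians of 0.96 and 1.00, and Ctss is in both the class II and the macrophage list, so the class II values are not separated from the share of leukocytes. The MHC class I genes were positive in 20 of 21, at a median of 0.40, with H2-K1 at 865 and 395 FPKM against 771 and 878 FPKM. Interferon response genes were positive in 24 of 29, at a median of 0.65, with Isg15 at 10.0 and 3.06 FPKM against 15.4 and 12.2 FPKM. Mx1, an antiviral GTPase, had the other sign, at 4.33 and 4.57 FPKM in KP and 2.16 and 2.27 FPKM in KP25. NF-kappaB and TNF response genes were positive in 19 of 26, at a median of 0.30. The adjusted p was 5.76e-05, 0.000125, 0.000121 and 0.00539 in this order (camera), each against 0.670 with an estimated correlation. None of the 4 passed without KP replicate 2 (0.555, 0.903, 0.874 and 0.497), and only the class II list kept its sign. The immune checkpoint and suppressive ligand genes did not pass (0.189), with Cd274, which encodes PD-L1, at 10.3 and 6.04 FPKM against 9.01 and 8.92 FPKM, and Cd276 at 8.17 and 10.1 FPKM against 4.84 and 6.17 FPKM.

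Several growth and metabolism lists were lower in KP25. All 24 NRF2 target genes, the antioxidant programme, were negative, at a median of -0.78, and KP replicate 2 was the highest library for all 24. Nqo1 was 2.48 FPKM in KP replicate 1 and 70.7 FPKM in KP replicate 2, against 3.41 and 3.02 FPKM in KP25. Gclc, which makes the first step of glutathione synthesis, was 175 and 395 FPKM against 120 and 169 FPKM. Glycolysis genes were negative in 19 of 20, at a median of -0.54, with the lactate transporter Slc16a3 at 5.3996 and 7.64 FPKM against 3.83 and 2.92 FPKM and the glucose transporter Slc2a1 at 11.6 and 25.8 FPKM against 10.2 and 9.84 FPKM. Cytosolic ribosomal protein genes were negative in 29 of 31, at a median of -0.25, and the MYC and ribosome biogenesis genes in 23 of 26, at a median of -0.18, with Nop56 at 16.8 and 19.4 FPKM against 13.3 and 13.2 FPKM and Myc at 12.7 and 23.6 FPKM against 11.1 and 10.4 FPKM. The adjusted p was 0.000205, 0.00173, 0.00539 and 0.0175 in this order (camera), against 0.670, or 0.683 for the ribosomal proteins, with an estimated correlation. None passed without KP replicate 2 (0.0549, 0.903, 0.0549 and 0.715), and only the MYC list kept its sign. The MYC list also missed the threshold without KP25 replicate 2 (0.0580).

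Mitotic genes were higher as a list, with 23 of 27 positive and a median of 0.35. Top2a was 4.75 and 1.51 FPKM in KP against 6.14 and 5.38 FPKM in KP25, and Mki67 was 7.33 and 2.35 FPKM against 6.63 and 6.55 FPKM. The 12 mitochondrially encoded genes had a median of 0.28, with 11 positive and mt-Nd5 at 950 and 1036 FPKM in KP against 1462 and 1422 FPKM in KP25. Of the 21 dissociation and immediate early genes 15 were positive, at a median of 0.19, with Jun at 48.7 and 27.6 FPKM against 60.6 and 60.9 FPKM. These 3 lists passed at an adjusted p of 0.000202, 0.000195 and 0.0356 (camera), each against 0.670 with an estimated correlation. Without KP replicate 2 the mitotic list did not pass (0.932), and the other 2 passed at 2.69e-07 and 0.0383, with medians of 0.36 and 0.06. Without KP replicate 1 the mitochondrially encoded list did not pass (0.142), nor did the immediate early list (0.251), which also missed it without KP25 replicate 2 (0.737).

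The remaining lists did not pass, with an adjusted p of 0.0568 for hypoxia response genes and between 0.102 and 0.847 for the others (camera). Hif1a, the oxygen-regulated transcription factor behind many of these genes, was 24.5 and 27.5 FPKM in KP and 18.5 and 17.6 FPKM in KP25, and 18 of 25 hypoxia response genes were negative, at a median of -0.29. Deubiquitinase and USP25 partner genes had a median of -0.05 over 28 members (0.561). The Wnt and beta-catenin targets had a median of -0.04 over 16 members (0.641), with Axin2 at 3.79 and 0.599 FPKM against 3.09 and 2.59 FPKM and Sox9 at 2.78 and 3.91 FPKM against 1.51 and 0.601 FPKM. MAPK output genes had a median of -0.03 and a mean of -0.05 with a test direction of higher (0.847). Median, mean and test also differed in sign for mesothelial markers (median -0.15, mean 0.07, higher), lipid synthesis genes (median 0.10, mean -0.01, higher) and TGF-beta response genes (median -0.01, mean 0.03, higher). The p53 target genes stood at 0.191, G1/S genes at 0.182, unfolded protein response genes at 0.182, YAP targets at 0.102, TGF-beta response genes at 0.641 and heat shock genes at 0.641. Sterol synthesis genes stood at 0.517, lipid synthesis genes at 0.561, oxidative phosphorylation genes at 0.714, club and secretory markers at 0.4998 and mesothelial markers at 0.514. Leaving out KP replicate 2, the oxidative phosphorylation and mesothelial lists passed as higher, both at 0.000766, with medians of 0.09 and 0.19. Scgb1a1 of club cells was 11124 and 2188 FPKM in KP against 14030 and 14181 FPKM in KP25. The club and secretory list as a whole was mixed, with 7 of 13 members positive and 6 negative. Among the negative ones, Muc5b was 5.87 and 10.3 FPKM in KP against 2.41 and 4.36 FPKM in KP25. Bpifa1 was 44.5 and 144 FPKM against 34.8 and 17.9 FPKM.

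**Figure D3:**
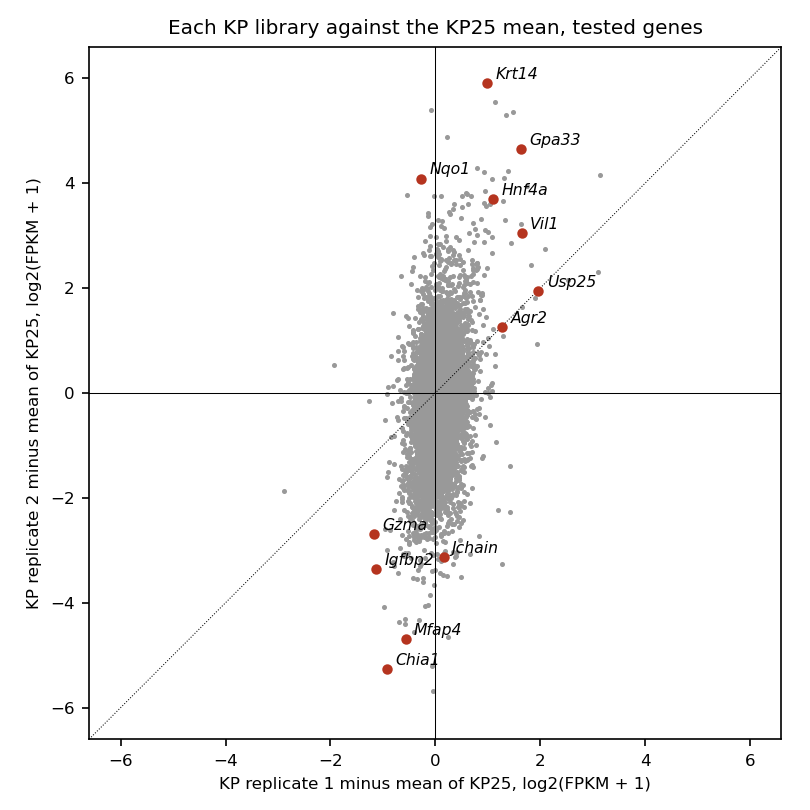
Difference of each KP library from the mean of the 2 KP25 libraries on the log2(FPKM + 1) scale for 12691 genes, KP replicate 1 horizontally and KP replicate 2 vertically, with 12 genes named in red and the line of equality dotted. The cloud is elongated along the axis of KP replicate 2, and Usp25 and Agr2 lie near the line of equality, while Nqo1 and Jchain differ mainly in KP replicate 2.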

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

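The alternatives were set before the data were examined, except limma-voom on the recovered reads, the fit without the trend, and the regrouped libraries. The planned edgeR and DESeq2 fits, with TMM factors, a CPM filter and another prior count, were not run, as the table holds no counts column. The recovered reads would have allowed them, and only voom was run on those reads. It is a different test and does not show what the planned fits would give. It called 0 genes, where the authors' deposited table has 6 with an adjusted p under 0.05. The count of 0 genes held with the authors' size factors, a pseudocount of 0.1, either filter, no robust estimation, no trend and voom, with between 14 and 7471 genes at an unadjusted p under 0.05 over all alternatives. Leaving out 1 library gave between 0 and 6740 genes (0 to 3305 higher, 0 to 3435 lower), and at a fold of 2 between 0 and 2294 (0 to 1456 higher, 0 to 838 lower). The 6740 came without KP replicate 1, when KP replicate 2 is the only KP library, and without KP replicate 2 there were 15; in both the spread comes from the KP25 pair alone. Without either KP25 library there were 0. The log2 fold change of Usp25 lay between -1.99 and -1.92 on leaving out 1 library and reached -2.25 with the pseudocount of 0.1; its adjusted p ranged from 3.55e-05 to 1.00 over the alternatives. With the replicate block 0 genes passed, Usp25 had an adjusted p of 0.929 and 27 lists passed. Same-numbered libraries did not deviate together (correlation -0.06), so the numbers were not read as pairs.

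The 25 lists became 0 with an estimated correlation (0 higher, 0 lower) and 0 with fry (0 higher, 0 lower), and 25 or 26 under each scaling, filter, rank and voom alternative. Leaving out 1 library gave between 10 and 27 lists, 9 to 19 higher and 1 to 9 lower, the lowest without KP replicate 2. Without that library 14 lists turned in direction, so their direction over the 4 libraries came from KP replicate 2. No biological reason for the departure of that library was tested. Of the 14 lists, unfolded protein response and sterol synthesis genes passed neither with nor without KP replicate 2. On leaving out 1 library the p of the others (camera, unadjusted) ranged from 2.23e-07 to 0.0221 for B and plasma cell markers, 8.44e-07 to 0.868 for MHC class I, 7.54e-05 to 0.248 for NF-kappaB, 1.90e-11 to 0.0149 for NRF2, 1.18e-09 to 0.510 for T and NK cells, 5.79e-05 to 0.873 for the advanced tumour state, 1.96e-06 to 0.0170 for ribosomal proteins, 1.70e-05 to 0.137 for epithelial adhesion, 1.08e-05 to 0.882 for glycolysis, 1.47e-08 to 0.784 for interferon response, 0.000109 to 0.872 for oxidative phosphorylation and 3.74e-05 to 0.309 for smooth muscle. The log2 fold change of mt-Nd1 ranged from -0.26, without KP replicate 1, to 0.34. Hypoxia response genes, at 0.0568, passed with the replicate block, ranks, the authors' size factors, the pseudocount of 0.1 and voom, and without any 1 library other than KP replicate 2. They did not pass without KP replicate 2 (0.514), with at least 1 FPKM in all 4 libraries (0.230), with an estimated correlation (0.670) or with fry (0.772). Simulated genes changed 4-fold were nearly all missed with each pair's own spread and recovered with that of the KP25 pair; what another depth would give was not simulated.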

Other observations

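Genes in this part were chosen after their values were seen. Over all genes, listed markers included, 59 genes were at least 2-fold higher in both KP libraries than in both KP25 libraries, and 7 had the opposite layout. The former include Usp25, Krt14 and the gastric and gut-like markers Agr2, Vil1, Foxa3, Gpa33 and Hnf4a. Of the unlisted ones, Cldn6, a claudin of fetal epithelium, was 11.0 and 23.1 FPKM in KP against 0.200 and 0.536 FPKM in KP25. Habp2 was 3.60 and 12.8 FPKM against 0.711 and 0.289 FPKM, the anticoagulant protein C gene Proc was 3.44 and 3.37 FPKM against 0.444 and 0.372 FPKM, and Dlk1 was 68.3 and 104 FPKM against 29.0 and 11.6 FPKM. Pyy, a gut peptide hormone, was 1.53 and 8.85 FPKM in KP and listed at 0 in both KP25 libraries. Igfbp2 is among the 7 higher in KP25. The rule set no floor on reads. The 59 include Gm17720, with 1 read in each KP library and 0 in each KP25 library. The 7 include Gm6020, with 0 and 1 reads in KP against 6 and 6 in KP25. None of these genes passed over all genes in the 4 libraries (limma, adjusted p of 0.776 for Cldn6).

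Some single genes were far from the other libraries in KP replicate 2, and no theme among them was tested. Krt5 stood at 59.4 FPKM against 0.219 to 0.517 FPKM in the other libraries, Psca at 66.7 against 0.0800 to 0.604 FPKM, Gkn2 at 1061 against 23.97 to 50.6 FPKM, and the tumour suppressor transcript Cdkn2a at 133 against 7.94 to 21.0 FPKM. The glutathione transferase Gstm1 was 1973 FPKM against 187 to 212 FPKM. The cardiac muscle genes Actc1 and Myh6 went the other way: Actc1 was 0.291 FPKM in KP replicate 2 and 45.8 to 92.4 FPKM in the others, and Myh6 was 0.290 FPKM against 15.7 to 26.1 FPKM. Y-linked Ddx3y and Eif2s3y were at 21.6 and 23.3 FPKM in KP25 replicate 2 and at or near 0 in the other 3 libraries. Y-linked Kdm5d and Uty had the same layout. By these transcripts KP25 replicate 2 came from a male mouse and the other libraries from female mice. Sex was therefore not balanced between the genotypes, and it was not a term in the fit.

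The tests of explanations below address patterns that had been seen in the results. Only for those on sampling noise and on the daily clock were the bounds written before the test was run. The first principal component, which separates KP replicate 2 from the other 3 libraries, took 89.5% of the variance. Sampling noise is argued against, since the component took 92.8% among the 3473 genes with a mean of at least 1000 reads, and a Usp25-deleted mouse under a KP label by its Usp25 level of 13.6 FPKM. An equal loss of RNA from all other cells is argued against as the whole cause. Relative to KP replicate 1, T and NK markers had a median of -2.41 log2 units and macrophage markers -0.44. The difference was -1.97 (permutation p = 0.00015, two-sided, across genes). That p treats genes as independent, while the T and NK members had a within-list correlation of 0.961, and it does not measure the spread between mice. Alveolar type 2 markers were lower (-0.88) while adhesion genes were higher (0.84). Type 2 markers can come from normal as well as tumour cells, so this does not decide the question. An unequal loss of other cells was not tested. A more advanced tumour or a difference in dissection may remain, and no biological explanation was tested. Of the 3 splits of the libraries into pairs, 2 gave at least the 25 lists called, the highest other split giving 25; 3 splits are too few for a share under 0.05.

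For the 66 genes at least 2-fold apart between the genotypes, 1 of 3 splits gave as many, the highest other split giving 21, again too few splits for a share under 0.05. A small share of cells like those of KP replicate 2 in KP replicate 1 could give the genes higher in both KP libraries. For this, 83 genes were chosen for being at least 8-fold higher in KP replicate 2 than in both KP25 libraries. Over them KP replicate 1 had a median of 4.91% of the excess over KP25 (quartiles 1.80% and 11.4%). Each KP25 library was measured likewise, but against KP replicate 1 and the other KP25 library, over 54 and 49 genes chosen anew. The medians were -0.11% and -1.93%, the first with an upper quartile that also came to 1.80%. An excess in KP replicate 1 raises that baseline and lowers these values, so part of the contrast is built in. KP replicate 1 had at least 50% of the excess for 19 of the 59 genes. They include Usp25, Agr2, Proc, Apob, Cfi and Per2, and also Gm17720 with 1 read in each KP library. Leaving Gm17720 aside, so large an excess is too much for a small share of such cells. However, the 59 were chosen for a 2-fold excess in KP replicate 1. For genes with a modest excess in KP replicate 2, such as Per2, that choice forces this result. For the other 40 such cells remain open with next to no margin, as does an effect of genotype. This measure replaced a first version, which parted the genes at 3 times the wide set's median (40 above it), after that version's values were seen, so it carries little weight.

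Per2 and Per3, parts of the circadian clock, were 17.7 and 15.2 FPKM and 8.89 and 12.2 FPKM in KP against 5.86 and 7.47 FPKM and 4.84 and 4.88 FPKM in KP25. Tissue taken at another phase of the daily clock might account for this. The 8 clock output genes had a median log2 fold change of -0.23, between the bounds set in advance, 2 of the 8 were lower in both KP25 libraries, and 4 genes of the opposite phase had a median of -0.01. This leaves the explanation open.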
